A study of Homo sapiens with 12 samples.

How the data were processed

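Small RNA of 70 to 300 nt from HEK293 cells was profiled by RiboMethSeq in 12 libraries, 4 each of siCtrl, siFBL and D97_133_KO. Per the labels, 100 ng of gel-purified RNA was denatured in 95% DMSO and hydrolysed at pH 9, 10 and 11 for 5, 10 and 15 minutes, and the labels do not tie these settings to replicates. The submitters' processing notes name Trimmomatic 0.36, STAR 2.7.9, bedtools and the build hg38; the bedtools version, the settings and the handling of reads that match several tRNA copies are not given in the sources used here.

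The deposited values are of 2 kinds, in 6 files, 1 per group and read end. The authors' counts are whole numbers of read 5' ends or 3' ends at each of 42640 nucleotides of 455 RNAs, per library and without normalization. The authors' score is a fraction from 0 to 1 per nucleotide and library, missing at low counts (39.3% of 5'-end and 40.0% of 3'-end values). Its formula was checked on the values: 100.0% of 302248 5'-end and 297584 3'-end scores equalled, within 1e-06, 1 minus the count over the mean of either the nearest neighbours or the 2 neighbours on each side with weights of 1 and 0.9, floored at 0. Reads that match several tRNA copies were not resolved: 9 initiator Met copies held between 22636.1 and 25859.5 read ends per library around position 34, so positions on near-identical copies are not separate measurements and totals may count a read more than once. For rRNA the row of the files was the nucleotide plus 1, checked on the control scores of known sites, and tRNA positions are the canonical ones given in the files.

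Ends on each bond were taken as 5' plus 3' ends. For each position, the ends at its bond and at 6 bonds on each side (at least 3 on a side) were compared in edgeR 4.0.16 with a library effect and a site-versus-flank effect per group over all 12 libraries, by quasi-likelihood F tests on contrasts, with a mean of at least 20 ends per window and Benjamini-Hochberg adjustment at 0.05 over all positions. A positive log2 change means more cleavage at the site relative to its flanks. A window holding a changed site also changes the flanks of its neighbours. Met-CAT 34 and the listed sites were tested with gene copies summed per family, with values adjusted over 13303 positions; of the 11 elongator Met copies 10 were testable at position 34. List shifts used the mean log2 ratio of site to flank per library, with a pseudocount of 0.5 ends, and exact two-sided permutation tests over 70 assignments. The 12 tests of shifts and of Met-CAT 34 were adjusted together by Benjamini-Hochberg. RNA abundance used 5' ends summed per RNA in edgeR with TMM and filterByExpr.

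The comparisons, the guided snRNA and 5.8S list (25 sites), the 3 stand-alone tRNA lists (16, 14 and 10 sites), the RNA classes, most alternatives and the rule for named items were chosen before the data were examined. The list of 108 sites in 18S and 28S rRNA was recalled from general knowledge after these RNAs were seen to be present and before its tests, and its positions were not checked against a database. By the rule, the text names Met-CAT 34, every guided site or its count, up to 4 stand-alone examples per list by highest control 3'-end score (in order of name where it was missing, as at most sites at positions 4 and 44), and per comparison the 10 rising and 10 falling positions and 5 rising and 5 falling RNAs with the smallest p. These had to lie outside the control range in all 4 libraries, with at most 1 per family and 1 per run of 3 adjacent positions. For the added list the 4 sites with the smallest p per comparison are named. scaRNAs, mitochondrial tRNAs, 5S rRNA and vault RNAs, and the snoRNAs that guide U6, were not analysed here.

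Alternatives were flanks of 2 bonds, 5' or 3' ends alone, replicate number as a block, the compared groups alone, other count minimums (none, 200), copies summed, limma 3.58.1 on the score, DESeq2 1.42.0, library size without TMM, no low-count filter, 3' ends for abundance, and each library left out in turn. Added after the data were seen were a minimum of 2-fold, siCtrl 1 and 2 or siCtrl 3 and 4 alone, positions without 18S and 28S rRNA, and calls by each read end alone. The fits were tested on simulated data with 200 changed features. Among 38420 positions, 76.1%, 85.1% and 93.9% of changes of 0.5, 1 and 2 (log2) were recovered with the siFBL design and 9 calls (5.03%) were false; with the D97_133_KO design the shares were 61.2%, 94.0% and 95.5%, with 3 false calls (1.76%). Among 443 RNAs 100% were recovered at each size in both designs, with 2 false calls (0.99%) for siFBL and 15 (6.98%) for D97_133_KO. Simulated positions were drawn independently, without overlapping windows or reads shared between tRNA copies. The shares of false calls therefore do not cover calls in the data that come from a changed neighbour or a near-identical copy. Both simulations gave all features a common spread, which for RNAs was estimated from tRNA alone. The shares for RNAs therefore do not cover the RNAs other than tRNA. For example, 7SK and 7SL, with a median log2 change of 1.48 in siFBL, were not called in the data. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read ends come from PCR-amplified libraries, so counts are not independent molecules. No reads were realigned and no sequence was used here.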

Results

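RiboMethSeq was used to map 2'-O-methyl groups (Nm) in small RNA of HEK293 cells, an established line from human embryonic kidney. In this assay an Nm protects the bond on its 3' side from alkaline hydrolysis, so few read ends fall at a methylated nucleotide and more fall there when the methyl group is lost. The 12 libraries came from 3 groups of 4: a control siRNA (siCtrl), an siRNA against FBL (siFBL), and cells with CRISPR deletions of the snoRNA genes SNORD97 and SNORD133 (D97_133_KO). FBL, fibrillarin, is the methyltransferase of the box C/D snoRNPs, in which a snoRNA guides the enzyme to its target. Per-nucleotide counts of read ends covered 455 RNAs, of which 430 were tRNA gene copies in 49 families and 25 were other RNAs.

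Depth ranged from 11515684 to 27666577 read 5' ends per library. The mean was 12668938 ± 1246189 (SD, n = 4) in siCtrl, 19144723 ± 6693582 in siFBL and 18655412 ± 4898329 in D97_133_KO. Nuclear tRNA held 92.5% ± 1.35 of the ends in siCtrl, 83.0% ± 8.81 in siFBL and 98.6% ± 0.206 in D97_133_KO. Fragments of 18S and 28S rRNA held 5.59% ± 0.968, 15.99% ± 8.26 and 0.723% ± 0.0587, respectively. SNORD97, SNORD133 and FBL had 0 nucleotides among the RNAs counted, so the deletions and the knockdown were not checked by the abundance of their targets. The same siCtrl libraries served as controls in both comparisons, and no unedited clone was used here as a control for the deletion. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples.

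The comparison of siFBL with siCtrl asked which Nm sites of small RNA depend on FBL. Elongator Met-CAT tRNA, which reads internal methionine codons, lost its protection at the wobble position 34, the site assigned to SNORD97 and SNORD133. The ratio of read ends at position 34 to the mean of its flanks was 0.264 ± 0.0404 (SD, n = 4) in siCtrl and 0.727 ± 0.0318 in siFBL, a log2 change of 1.47 ± 0.0933 (SE; edgeR adjusted p = 1.82e-07), with 4 of 4 libraries above all controls. The authors' 3'-end score, near 1 at a protected nucleotide and 0 at an unprotected one, went from 0.690 ± 0.105 to 0.0731 ± 0.0639, and the 5'-end score from 0.652 ± 0.0591 to 0.208 ± 0.0401. An exact two-sided permutation test gave p = 0.0286 for the ratio and for each score (n = 4 per group), the smallest p that 70 assignments allow. Read ends at position 34 rose in 10 of the 10 tested gene copies, and the copy on chromosome 8 (hg38, 123157230 to 123157302) had the smallest p of all positions, with a log2 change of 1.82 ± 0.107 (edgeR adjusted p = 1.08e-07). Reads shared between copies were not resolved, so the 10 copies are not separate measurements. In initiator Met tRNA, named after its values were seen, position 34 had a 3'-end score of 0 in all 3 groups and a log2 change of 0.26 in siFBL on the chromosome 1 copy (153671250 to 153671321; edgeR adjusted p = 0.023).

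**Figure D1:**
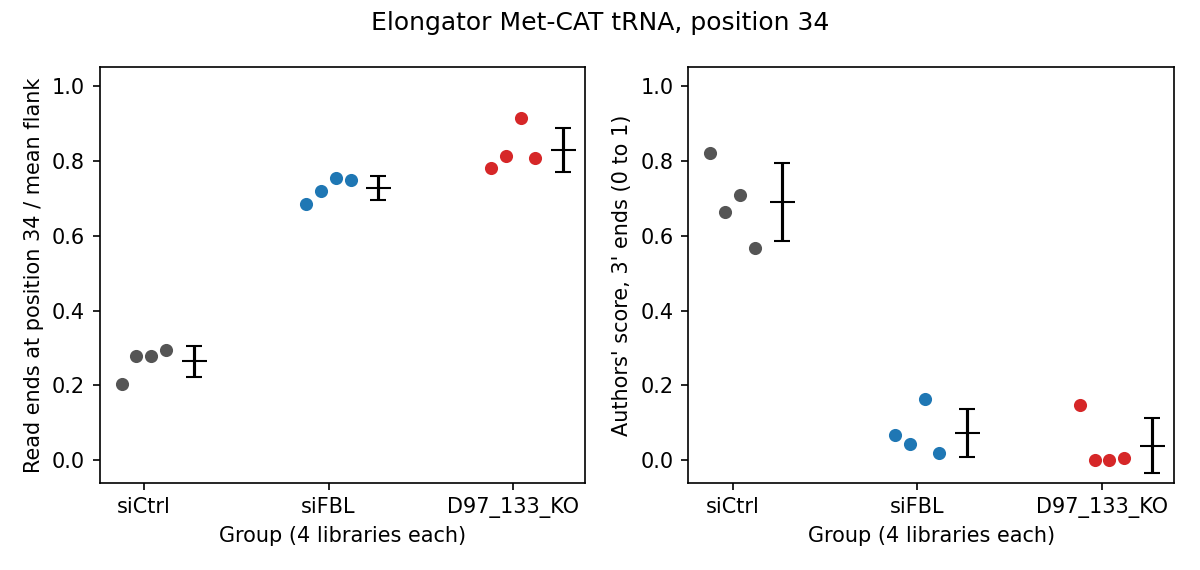
Position 34 of elongator Met-CAT tRNA, gene copies summed: the left axis gives read ends at the position divided by the mean of its flanks, the right axis the authors' 3'-end score from 0 to 1; points are libraries and bars the mean ± SD of 4. The siCtrl ratios lie between 0.204 and 0.294, all below the siFBL ratios (0.685 to 0.755) and the D97_133_KO ratios (0.782 to 0.916).

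RNA-guided sites in spliceosomal snRNAs also lost protection in siFBL. Of the 25 listed sites in snRNA and 5.8S rRNA, 7 rose, 0 fell and 22 had a positive log2 change; adjusted over the list alone, 9 rose and 0 fell. The largest rise was at Um47 of U2, the snRNA that pairs with the branch site, where the ratio to the flanks went from 0.192 ± 0.0760 to 0.703 ± 0.233 (log2 1.95 ± 0.265 SE, n = 4; edgeR adjusted p = 0.000528), in 4 of 4 libraries above all controls. In U6, the snRNA at the catalytic centre of the spliceosome, 5 sites rose: Am70 by 1.06 ± 0.114, Cm63 by 0.86 ± 0.117, Am53 by 0.67 ± 0.115, Cm62 by 0.61 ± 0.113 and Am47 by 0.59 ± 0.0849, all log2. The remaining call was Am70 of U1, the snRNA that recognises the donor splice site, with a log2 change of 0.77 ± 0.135. The list as a whole shifted by 0.44 (log2; -1.43 ± 0.116 against -1.87 ± 0.0655), with each of the 4 siFBL libraries above all controls (exact two-sided permutation p = 0.0286, BH-adjusted over 12 tests 0.049). By 5' ends alone the shift was 0.36. By 3' ends alone, at 21 sites, it was 0.82, and Am53 of U6 was not called (log2 0.46).

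Sites in 18S and 28S rRNA, the RNAs of the small and large ribosomal subunits, moved the same way in siFBL. Of all 6929 positions tested in these RNAs, 282 rose and 352 fell (edgeR, adjusted over 38420 positions). Among 108 guided sites recalled from general knowledge, 34 rose and 4 fell. Adjusted over the list alone these counts were 48 and 9. By 5' ends alone 19 rose and 0 fell, by 3' ends alone 26 rose and 9 fell, and the count of falls was 1 to 6 with 1 library left out. At 28S Nm2861 the 3'-end score fell from 0.491 ± 0.0565 to 0.0074 ± 0.0149 (log2 change of read ends 1.29 ± 0.119 SE, n = 4; edgeR adjusted p = 3.05e-05, 4 of 4 libraries outside the controls). Log2 changes were 1.49 ± 0.187 at 28S Nm4227, 1.23 ± 0.141 at Nm2422 and 0.73 ± 0.104 at Nm2876. The mean shift over the list was 0.24 (log2), with 4 of 4 siFBL libraries above the controls (exact two-sided permutation p = 0.0286, BH-adjusted 0.049). With any 1 of the siFBL libraries left out, the shift lay between 0.23 and 0.25 and its exact permutation p was 0.0571.

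Few sites made by stand-alone tRNA methyltransferases, which need no guide RNA, rose in siFBL. A loss could be seen only where the controls showed protection, and a control 3'-end score over 0.5 was found at 9 of 16 sites at positions 32 and 34 and 7 of 14 at position 18. At positions 4 and 44 this score was missing at 9 of 10 sites. At positions 32 and 34, sites of FTSJ1, 1 of 16 rose (Thr-TGT 32, log2 0.24, where the control ratio was already 2.57) and 3 fell: Phe-GAA 32 by -1.24 ± 0.158, Leu-AAG 32 by -0.52 ± 0.0802 and Leu-TAA 34 by -0.32 ± 0.0930. At position 18, the site of TARBP1, 0 of 14 rose and 2 fell, Ser-AGA by -0.63 ± 0.103 and Ser-TGA by -0.51 ± 0.108. At positions 4 and 44, sites of TRMT13 and TRMT44, 0 of 10 rose and 6 fell, including position 4 of Pro-AGG (-1.75 ± 0.214), Pro-CGG (-1.73 ± 0.201) and Pro-TGG (-1.62 ± 0.207). Control ratios at position 44 of Ser-AGA, Ser-CGA and Ser-TGA were 1.77, 3.81 and 1.91, so the absence of rises at these 3 sites cannot be read as methylation kept. The same limit applies at position 4 of Gly-GCC (0.95), Gly-CCC (1.14) and His-GTG (1.09), with control ratios near 1. The Pro sites had control ratios of 0.0577 to 0.0599. Adjusted over the list alone, the counts risen and fallen were 1 and 4, 1 and 3, and 0 and 8. The examples taken by control 3'-end score (by name where it was missing) that were not called had log2 changes of 0.11 (Gln-CTG 32), 0.01 (Leu-TAG 32), 0.10 (Arg-CCG 32), -0.35 (Ser-GCT 18), -0.26 (Ser-CGA 18), -0.20 (Ser-GCT 44), 0.0013 (Gly-CCC 4), -0.085 (Gly-GCC 4) and -0.21 (His-GTG 4). Over all 40 sites the shift was -0.25 (log2; exact two-sided permutation p = 0.0571, n = 4 per group), and it passed the test without siCtrl 1 (-0.33, p = 0.0286) but was -0.15 with siCtrl 1 and 2 as the controls. By 5' ends alone the change at Ser-AGA 18 was 0.032 and neither Leu-AAG 32 nor Ser-TGA 18 was called. By 3' ends alone Leu-TAG 32 fell by 0.69 and 0 sites were called as fallen at positions 4 and 44. However, 34 of the 40 sites had enough 3' ends to test, and an untested site counted as not fallen. The count of 0 is therefore no check on the falls at positions 4 and 44. Thr-TGT 32, Leu-TAA 34 and the Pro sites of this list were named after their values were seen.

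Among the 10 named rises in siFBL the largest was in a tRNA copy that the lists hold only as part of its family. A copy of Leu-CAA tRNA on chromosome 11 (9275243 to 9275316) rose at position 34 by 2.35 ± 0.203 (log2, SE), while the other 6 Leu-CAA copies were not called there and the family as a whole had a log2 change of -0.09. No sequence was used here to tell whether the reads of this copy came from another tRNA. Other rises were at 18S nucleotide 624 (0.79), Ala-AGC 19 (0.59), Ala-TGC 19 (0.58), Trp-CCA 26 (0.54), Ser-AGA 21 (0.52) and Glu-CTC 49 (0.26). The authors' control score was 0 from both ends at Ala-AGC 19 and Ser-AGA 21, and 0 from 5' ends and missing from 3' ends at Trp-CCA 26. At these positions no protection was measured that could be lost. The named falls were Pro-CGG 4 (-1.9986) and Pro-AGG 4 (-1.97), Asn-GTT 16 (-1.68), 28S nucleotide 2884 (-1.35), Phe-GAA 32 (-1.32), 18S nucleotide 178 (-1.03), Met-CAT 31 (-0.77, inside the window of position 34), Val-CAC 47 (-0.45), Glu-CTC 20a (-0.26) and Gly-GCC 20 (-0.24). Each tRNA value is that of the copy with the smallest p. Other copies were called too, such as 4 of 4 for Pro-CGG 4, 9 of 9 for Pro-AGG 4 and 12 of 14 for Gly-GCC 20, though near-identical copies are not separate measurements. In contrast, Ala-AGC 19 was called in 6 of 26 copies, and its family as a whole (0.22) was not called. Of 17 named positions testable from each end, 6 were called the same way by 5' ends alone and by 3' ends alone, 7 were lost by an end and 4 changed sign by an end (Ser-AGA 21, Trp-CCA 26, 18S nucleotide 178 and Glu-CTC 20a). In all, 4129 of 38420 positions passed (edgeR, BH 0.05), 1842 risen and 2287 fallen, of which 234 changed at least 2-fold (55 risen, 179 fallen). With gene copies summed per family the count was 945 of 13303. It was 2029 with the siCtrl and siFBL libraries fitted alone and 1678 with limma on the score computed here. It was 1718 without siFBL 1, 2083 without siCtrl 4 and 2094 without siFBL 3.

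When a call was asked of each read end alone, a criterion chosen after the data were seen, guided sites made up most of the rises in siFBL. Of 12289 positions, 23 rose and 31 fell by both ends, and 17 of the 23 rises were at the 130 guided sites tested, where 0.243 would fall by chance (Fisher's exact test, two-sided p = 8.44e-30). These 17 included Met-CAT 34, U2 Um47, U1 Am70, U6 Am47, Cm62, Cm63 and Am70, and 28S Nm2861, Nm2422, Nm2876 and Nm4227. None of the 31 falls was at a guided site and 1 was at a stand-alone site, Phe-GAA 32. With 130 guided sites among 12289 positions, chance too would most likely place no fall at a guided site, so their absence shows little. Some falls, such as Met-CAT 28 and Met-CAT 31, lay in the window of a guided site that rose and are not separate from that rise. A further 15 positions were called in opposite directions by the 2 ends. Fisher's test counted positions as independent, although their windows overlap and all calls share the same libraries. Its p-value therefore does not measure the spread between libraries.

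**Figure D2:**
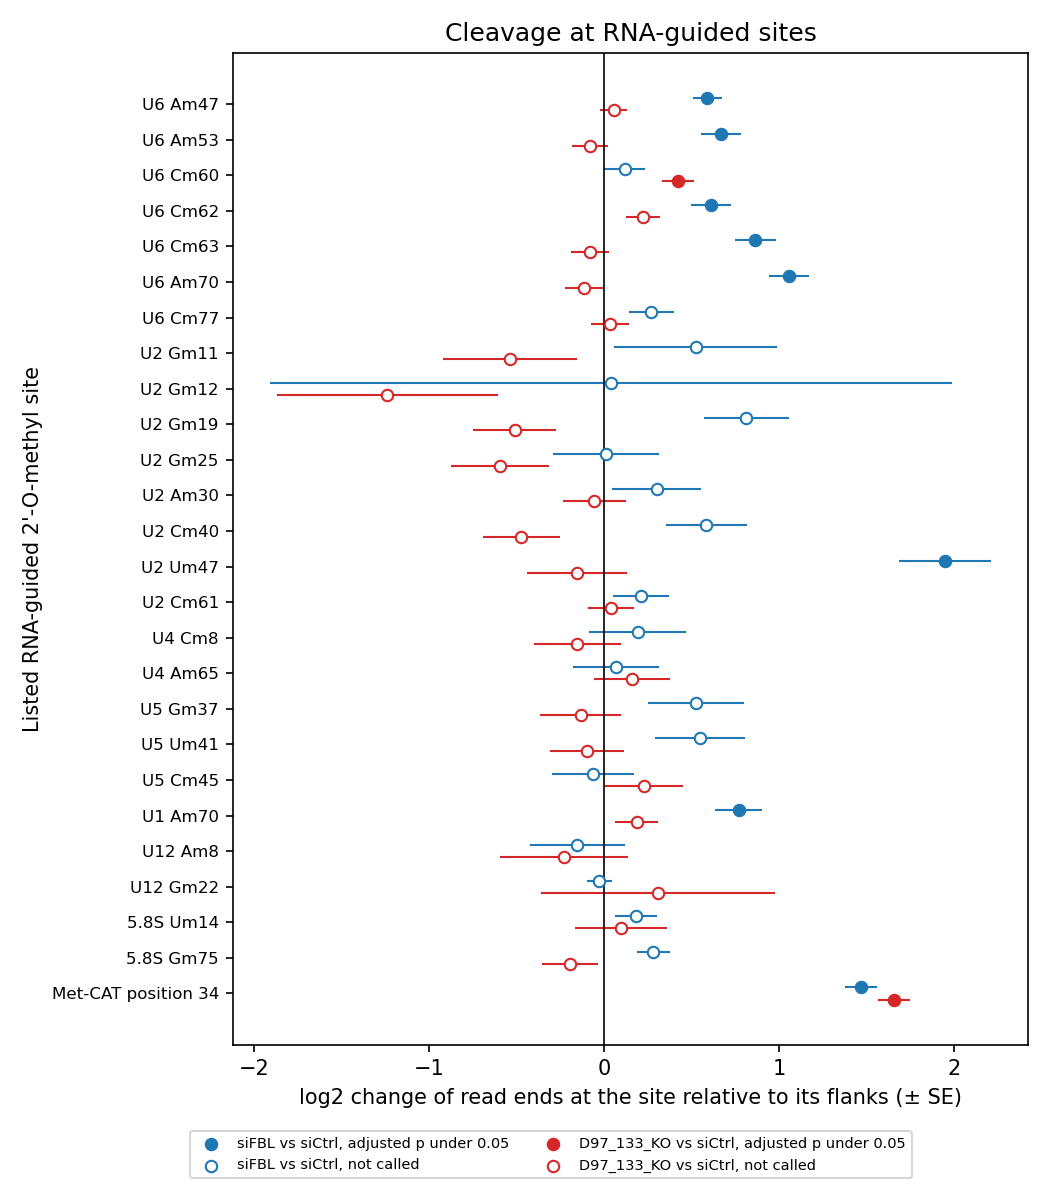
Log2 change of read ends at each listed RNA-guided site relative to its flanks (horizontal axis, ± SE) in siFBL (blue) and D97_133_KO (red) against siCtrl; filled points have an adjusted p under 0.05. Filled blue points lie at 7 of the 25 snRNA and 5.8S rRNA sites, and Met-CAT position 34 is filled in both colours (1.47 and 1.66).

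RNA abundance in siFBL differed most among the RNAs other than tRNA. All 9 spliceosomal snRNAs fell, with a median log2 change of -1.80, from U12 of the minor spliceosome (-3.28 ± 0.449 SE, n = 4) through U6 (-1.80 ± 0.158) and U11 (-1.74 ± 0.208) to U4atac (-1.17 ± 0.333). The size of these falls depends on the controls, in which snRNA held 1.60% and 2.003% of the 5' ends (siCtrl 1 and 2) or 0.855% and 0.919% (siCtrl 3 and 4), while it held at most 0.299% in siFBL. The values of U4atac and U13 overlapped the controls in at least 1 library, and those of 18S rested most on siFBL 4, which held 14.3% of its ends there. Of 5 box C/D snoRNAs, which bind FBL, 3 fell: U8, needed for processing of large-subunit rRNA, by -3.12 ± 0.273, U14B by -2.03 ± 0.409 and U13 by -1.98 ± 0.567. Fragments of 28S rRNA rose by 1.68 ± 0.250 and those of 18S by 2.37 ± 0.583, while 7SK and 7SL each had a log2 change of 1.48 and were not called. Of 4 Y RNAs 2 fell (RNY2 by -0.83, RNY4 by -0.54), and U7 fell by -0.34. Named tRNA copies changed little: Glu-TTC on chromosome 13 rose by 0.38, Gly-TCC on chromosome 1 by 0.26, Val-TAC on chromosome 11 by 0.24 and Leu-AAG on chromosome 6 by 0.21, and Ser-CGA on chromosome 17 fell by 0.47. In edgeR 174 of 443 RNAs passed, 100 risen and 74 fallen, and 67 with the siCtrl and siFBL libraries fitted alone. Scaling by library size alone moved the median of all RNAs to -0.304 and gave 13 rises and 315 falls; Val-TAC, Leu-AAG and Gly-TCC then had a negative sign and Glu-TTC was not called. With siCtrl 1 and 2 as the controls the rise of Leu-AAG was 0.12. U4atac, U14B, U13, RNY2, RNY4, U7, 18S, 7SK and 7SL were named after their values were seen.

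The comparison of D97_133_KO with siCtrl asked which Nm sites need the snoRNAs SNORD97 and SNORD133. Their assigned target, position 34 of elongator Met-CAT tRNA, lost its protection: the ratio to the flanks was 0.264 ± 0.0404 (SD, n = 4) in siCtrl and 0.830 ± 0.0593 in D97_133_KO, a log2 change of 1.66 ± 0.0916 (SE; edgeR adjusted p = 1.29e-09), with 4 of 4 libraries above all controls. The 3'-end score went from 0.690 ± 0.105 to 0.0389 ± 0.0733 and the 5'-end score from 0.652 ± 0.0591 to 0.0011 ± 0.0018. For the ratio and each score the exact two-sided permutation p was 0.0286 (n = 4 per group), again the smallest possible. Read ends rose at position 34 in 10 of 10 tested copies, which are not separate measurements, by 1.95 ± 0.103 (log2) on the chromosome 8 copy. At position 34 of initiator Met tRNA the log2 change was -0.11 on the chromosome 1 copy and was not called. The abundance of elongator Met-CAT copies went both ways: a chromosome 6 copy (26766234 to 26766306) rose by 0.29 ± 0.0323 (log2) and the chromosome 8 copy, looked up after its values were seen, fell by 0.47, with reads shared between copies not resolved.

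Few calls were made at other guided sites in small RNA. Of the 25 listed sites 16 had a control 3'-end score over 0.5, and a loss could be missed at some of the rest. Others of the rest lacked this score but were protected by other values, such as U5 Cm45 (control ratio 0.118, 5'-end score 0.909). Of the 25 snRNA and 5.8S rRNA sites 1 rose and 0 fell, and the same counts held adjusted over the list alone. The site was Cm60 of U6 (log2 0.42 ± 0.0907 SE, n = 4; edgeR adjusted p = 0.00256, 4 of 4 libraries outside the controls), which was not called from 3' ends alone. Without siCtrl 2, Cm62 of U6 rose as well (log2 0.33) and Cm40 of U2 fell (-0.66). The list shift was -0.15 (log2; exact two-sided permutation p = 0.171, n = 4 per group), and without D97_133_KO 2 it was -0.20 with p = 0.0286. Called stand-alone tRNA sites had fewer read ends than in siCtrl, which for position 44 of Ser-AGA, Ser-CGA and Ser-TGA left ratios to the flanks of 1.49, 2.19 and 1.52, still above 1. At positions 32 and 34, 0 of 16 rose and 4 fell: Phe-GAA 32 (-0.89 ± 0.150), Leu-AAG 32 (-0.77 ± 0.0802), Leu-TAA 34 (-0.33 ± 0.0910) and Trp-CCA 34 (-0.26 ± 0.0843). At position 18, 0 of 14 rose and 2 fell (Ser-AGA -0.49, Ser-TGA -0.39); at positions 4 and 44, 0 of 10 rose and 7 fell, among them Ser-CGA 44 (-0.79), Ser-GCT 44 (-0.42) and Pro-AGG 4 (-1.12). Adjusted over the list alone, the counts risen and fallen were 2 and 6, 0 and 2, and 0 and 7, the rises being Arg-TCG 32 (0.20) and Arg-CCG 32 (0.24), named after their values were seen. Examples not called were Gln-CTG 32 (0.11), Leu-TAG 32 (-0.03), Arg-CCG 32 (0.24), Ser-GCT 18 (-0.26), Ser-CGA 18 (-0.20), Gly-CCC 4 (-0.12), Gly-GCC 4 (-0.14) and His-GTG 4 (-0.081). The shift over the 40 sites was -0.21 (exact two-sided permutation p = 0.143), and it was -0.29 with p = 0.0286 without siCtrl 1 and -0.11 with siCtrl 1 and 2 as the controls. By 5' ends alone the change at Ser-AGA 18 was 0.044, and 0 sites fell at positions 32 and 34 or at position 18. By 3' ends alone 0 were called as fallen at positions 4 and 44. As in siFBL, 34 of the 40 sites had enough 3' ends to test and an untested site counted as not fallen, so this is no check. Leu-TAA 34, Trp-CCA 34 and Pro-AGG 4 were named after their values were seen.

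Most of the positions called in D97_133_KO lay in RNAs with no assigned target of these snoRNAs, and many depended on which read end was counted. The 18S and 28S rRNA, at 0.723% of the read ends in these libraries, held 1860 called positions of 6929 tested, 723 risen and 1137 fallen. Largest among the named rises, beside Met-CAT 34 on chromosome 8 (1.95), were 28S nucleotide 2061 (3.00 ± 0.132, log2, SE), the Leu-CAA copy on chromosome 11 at position 34 (2.68 ± 0.189), 18S nucleotide 1538 (2.24 ± 0.0922) and 5.8S nucleotide 50 (1.47 ± 0.163). By 5' ends alone the changes at 28S nucleotide 2061 (0.13) and 18S nucleotide 1538 (0.43) were not called. Of the other 6 Leu-CAA copies, 4 fell at position 34 and none rose, so the copy on chromosome 11 stood apart, and the source of its reads was not resolved. Smaller named rises were Ser-TGA 32 (1.09), Tyr-GTA 46 (0.67), Arg-CCT 66 (0.65), Ala-TGC 46 (0.64) and Ser-AGA 21 (0.52). The authors' control score was 0 from both ends at 5.8S nucleotide 50 and Ser-AGA 21. At 18S nucleotide 1538 it was 0 from 5' ends and 0.0024 from 3' ends. At these positions hardly any protection was measured that could be lost. Named falls were 18S nucleotide 1677 (-1.97), 28S nucleotide 523 (-1.69), Ala-AGC 55 (-0.96), Ser-TGA v5 (-0.93), Ser-AGA v6 (-0.81), Ser-CGA 44 (-0.76), Glu-CTC 54 (-0.58), Thr-TGT 60 (-0.56), Cys-GCA 28 (-0.44) and Leu-CAG v9 (-0.36). Each tRNA value is that of the copy with the smallest p. With copies summed per family, Ser-TGA 32 (0.068), Ala-TGC 46 (0.10), Tyr-GTA 46 (0.15) and Thr-TGT 60 (-0.17) were not called. Of 17 named positions testable from each end, 2 were called the same way by both, 8 were lost by an end and 7 changed sign by an end (Ser-TGA 32, Ser-AGA 21, Tyr-GTA 46, 18S nucleotide 1677, Ser-CGA 44, Thr-TGT 60 and Cys-GCA 28).

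Of all 6929 positions tested in 18S and 28S rRNA, 723 rose and 1137 fell in D97_133_KO (edgeR, adjusted over 38420 positions). At the 108 recalled sites of these RNAs, 26 rose and 11 fell (26 and 14 adjusted over the list alone), and by 5' ends alone 9 rose and 5 fell, by 3' ends alone 12 and 3. The smallest p belonged to 18S Nm683 (log2 1.80 ± 0.186 SE, n = 4; control 3'-end score 0), 18S Nm601 (1.44 ± 0.157), 28S Nm3869 (1.46 ± 0.171) and 28S Nm3887 (1.64 ± 0.196). By 5' ends alone Nm683 and Nm3887 changed sign, and by 3' ends alone Nm601 was not called. The mean difference over the list was 0.04 (log2; exact two-sided permutation p = 0.571, n = 4 per group), and its sign was not fixed: -0.0013 without siCtrl 3, 0.08 without siCtrl 2, -0.0048 by 5' ends and 0.14 by 3' ends.

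In all, 5231 of 38420 positions passed in D97_133_KO (edgeR, BH 0.05), 2113 risen and 3118 fallen, of which 910 changed at least 2-fold. The count was 2815 of 13303 with gene copies summed per family, 2956 without 18S and 28S rRNA and 2712 from 3' ends alone. By each read end alone, 65 positions rose and 128 fell of 12289, and 136 were called in opposite directions; 169 of the calls were in 18S and 28S rRNA. Of the 65 rises 4 were at guided sites, where 0.688 would fall by chance (Fisher's exact test, two-sided p = 0.00492): Met-CAT 34, 18S Nm621, 28S Nm3825 and 28S Nm3869. Within 18S and 28S rRNA, with 59 of the rises, the 3 at guided sites against 0.921 by chance did not pass (Fisher's exact test, two-sided p = 0.0641). As in siFBL, positions are not independent replicates in these tests. Outside rRNA 5 rose and 17 fell of 5219, all in tRNA, and of these Met-CAT 34 was the guided site. For spliceosomal snRNA the count by both ends was 0 of 887 (edgeR); with both ends summed it was 15 of 1161, with 103 at an unadjusted p under 0.05.

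Abundance in D97_133_KO was lower for most of the longer RNAs. The signal recognition particle RNA 7SL had a log2 change of -5.32 ± 0.752 (SE, n = 4), 7SK, which holds back the elongation factor P-TEFb, -4.52 ± 0.749, U3 of the box C/D class -3.59 ± 0.730 and U17 of the box H/ACA class -3.32 ± 0.705. Fragments of 28S and 18S rRNA fell by -3.05 ± 0.263 and -2.96 ± 0.597, 7 of 9 spliceosomal snRNAs fell (median -1.58), and all 4 Y RNAs fell, RNY4 by -1.36 ± 0.139. U7, which processes histone mRNA, fell by -0.89. Over the 23 RNAs other than tRNA, 18S and 28S, the log2 change went down with RNA length (Spearman -0.656), and the difference between siCtrl libraries 3 and 4 and siCtrl libraries 1 and 2 did so too (-0.904), while in siFBL the value was 0.0395; these are correlations across RNAs, which are not independent replicates. The controls formed 2 sets, in which 7SK and 7SL together held 0.186% and 0.178% of the 5' ends (siCtrl 1 and 2) against 0.0307% and 0.0346% (siCtrl 3 and 4), and snRNA 1.60% and 2.003% against 0.855% and 0.919%, so the size of these falls depends on the controls. Named tRNA copies that rose were Ala-AGC (0.71 ± 0.0485, chromosome 6, 28838444 to 28838515), Ala-TGC (0.51 ± 0.0432), Ala-CGC (0.28 ± 0.0319) and Val-TAC (0.26 ± 0.0256), and those that fell were another Ala-AGC copy (-1.29 ± 0.0977, chromosome 6, 57815974 to 57816046) and Asn-GTT on chromosome 1 (-0.79 ± 0.0962). In edgeR 212 of 443 RNAs passed, 110 risen and 102 fallen, and 121 when scaled by library size alone, which moved the median of all RNAs to 0.0622. U3, U17, 7SK, 7SL and 18S were named after their values were seen.

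**Figure D3:**
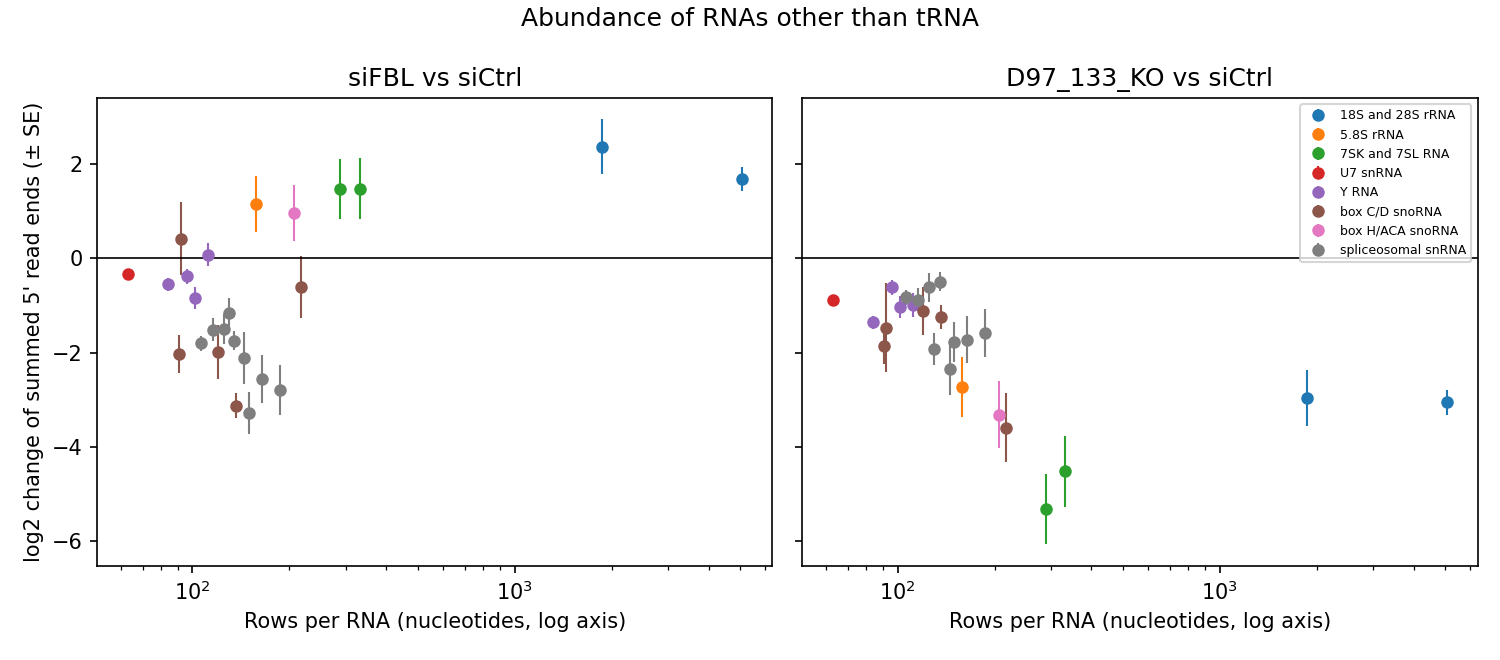
Log2 change of read 5' ends summed per RNA (vertical axis, ± SE) against RNA length in nucleotides (log axis) for the 25 RNAs other than tRNA, in siFBL (left) and D97_133_KO (right) against siCtrl. Spliceosomal snRNAs (grey) lie below 0 in both, and 7SK and 7SL (green) lie at 1.48 in siFBL and at -4.52 and -5.32 in D97_133_KO.

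A direct test of D97_133_KO against siFBL separated Met-CAT 34 from the snRNA sites. The snRNA and 5.8S rRNA list was lower in D97_133_KO by -0.58 (log2), with 4 of 4 libraries below all siFBL libraries (exact two-sided permutation p = 0.0286, n = 4 per group, BH-adjusted 0.049). The difference was -1.17 at U6 Am70 (edgeR adjusted p = 7.34e-07), -0.94 at U6 Cm63 (1.13e-05), -2.11 at U2 Um47 (3.57e-05), -0.75 at U6 Am53 (0.000115), -0.54 at U6 Am47 (0.000138), -0.58 at U1 Am70 (0.00556) and -0.39 at U6 Cm62 (0.0163). At Met-CAT 34 it was 0.19, which passed the exact permutation test on the log2 ratio (two-sided p = 0.0286, BH-adjusted 0.049) and missed the edgeR threshold (adjusted p = 0.129). The 18S and 28S list differed by -0.19 (exact permutation p = 0.0286) and the stand-alone list by 0.04 (exact permutation p = 0.143).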

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

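The tests of other splits of the libraries and of the snRNA pattern were chosen after the results were seen, and the tests of the Leu-CAA and rRNA patterns before their own values were seen.

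Within groups of 4, 11 of 54 sets of values held a library that passed the critical value of Dixon's test, where chance marks about 1 in 20. Most of these were in siFBL 4, which held more rRNA: 18S and 28S made up 28.3% of its 5' ends (11.3% to 12.7% in the other siFBL libraries), 18S alone 14.3% (2.66% to 3.08%), 5.8S rRNA 0.931% (0.193% to 0.261%) and nuclear tRNA 69.9% (86.5% to 88.1%). The same library held 0.0471% box C/D snoRNA (0.0135% to 0.0186%) and 0.0076% box H/ACA snoRNA (0.0021% to 0.0028%), and its mean log2 ratio over the stand-alone list was -1.51 (-1.62 to -1.61). In siCtrl 3 the mean log2 ratio over the guided list was -1.77 (-1.91 to -1.89 in the other controls). At Met-CAT 34 the log2 ratio of siCtrl 1 was -2.29 (-1.85 to -1.76), the 3'-end score of D97_133_KO 1 was 0.149 (0 to 0.0069) and the 5'-end score of D97_133_KO 4 was 0.0038 (0 to 0.0006). The 54 sets are not independent, since shares of read ends within a library depend on each other, and the D97_133_KO scores lay near the floor of 0. The 11 flags therefore overstate the excess over chance.

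Chance assignment of libraries is argued against for all 4 counts, since each was reached by 1 of 35 splits, the real one. That is the lowest share 35 splits allow, and it was not adjusted over the 4 counts. The splits cannot tell the treatment from any other difference between the groups. Fitted on the compared groups alone, siFBL gave 2029 positions and at most 150 in another split, which exchanged siCtrl 3 and siFBL 4, and D97_133_KO gave 4490 and at most 0. For RNA abundance the counts were 67 and at most 0 in siFBL, and 206 and at most 0 in D97_133_KO.

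The Leu-CAA copy on chromosome 11 lost protection at position 34 in both comparisons (log2 2.35 and 2.68). It held 1085.8 read ends per control library, and its length of 74 nt is nearer the 73 nt of the elongator Met copies than the 84 to 108 nt of the other Leu-CAA copies. Reads of whole elongator Met tRNA counted at this copy are argued against by its control profile, which correlated at a median of 0.0224 with the 11 Met copies (-0.115 to 0.229) where over 0.8 would be needed, though also at only -0.317 with the other Leu-CAA copies. A subset of Met fragments that matches part of this copy, or a guided site of its own, may account for it, and neither was tested because no sequence was used here.

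In D97_133_KO 1860 of 6929 positions of 18S and 28S rRNA were called. Of the called positions 21.8% lay within 6 nucleotides of a listed site, against 16.02% of those tested, which meets the bound against loss of Nm at listed sites as the whole cause, but siFBL gave 29.8% and would meet it too, so the test separates little and a part for Nm loss stays open. A difference of the kind seen among controls cannot be told apart: the log2 change correlated at -0.147 with siCtrl 3 and 4 minus siCtrl 1 and 2 (-0.285 over called positions), between the bounds of 0.1 and 0.3 set beforehand. The other control splits gave 0.297 (siCtrl 2 and 4 minus 1 and 3) and 0.0044 (2 and 3 minus 1 and 4), and the knockout change was wider (SD 0.596) than the control difference (0.199). Differences in which rRNA fragments entered the size range, with 0.723% rRNA in these libraries against 5.59%, may contribute and were not tested, nor was any biological cause.

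In siFBL all 9 spliceosomal snRNAs fell, by a size that depends on the controls (1.60% and 2.003% of the 5' ends in siCtrl 1 and 2, 0.855% and 0.919% in siCtrl 3 and 4). RNAs over 200 nt had a median log2 change above that of RNAs of 100 to 200 nt by 3.00 (1.22 over 4 RNAs against -1.77 over 14), although those 4 were not called one by one. This argues against a recovery that drops with RNA length, but the bound was set after the values were known, so it is no independent test. The rise of long RNAs also depends on the controls. The 7SK and 7SL share was 0.126% to 0.404% in siFBL, 0.186% and 0.178% in siCtrl 1 and 2, and 0.0307% and 0.0346% in siCtrl 3 and 4. The mean of box C/D RNAs relative to the snRNAs was higher in siFBL by 0.434 (log2; -3.92 ± 0.497 against -4.35 ± 0.0812; exact two-sided permutation p = 0.114, n = 4 per group), though the class medians were -1.98 and -1.80, so a loss specific to box C/D RNAs was not seen and is not settled. In D97_133_KO, without the knockdown, it was lower by -0.505 (exact permutation p = 0.0286, the smallest possible, 4 of 4 libraries below all controls). An effect of FBL loss on snRNAs stays open, as do differences in RNA quality or size selection between siFBL and siCtrl, which were not tested.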

How the results depend on the processing

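The 2-fold minimum, the subsets of controls, the omission of 18S and 28S rRNA and the calls by each read end were chosen after the data were seen. Met-CAT 34 was called in the same direction by edgeR or limma under every alternative run, with log2 changes of 1.36 to 1.53 (siFBL) and 1.54 to 1.72 (D97_133_KO) as each library was left out; its exact permutation p was 0.0667 with either pair of controls and 0.125 with the replicate block, the smallest these allow. Counts of positions depended most on the settings. In siFBL 4129 became 2029 with the compared groups alone, 945 with copies summed, 1678 with limma on the score computed here, 234 at 2-fold and 54 by both ends alone. It became 1718 to 4966 as each library was left out (1718 without siFBL 1, 2083 without siCtrl 4, 2094 without siFBL 3). In D97_133_KO 5231 became 2712 from 3' ends, 2815 with copies summed, 910 at 2-fold, 2956 without 18S and 28S rRNA, 193 by both ends alone, and 3567 to 5430 as each library was left out. RNA counts became 328 (siFBL) and 121 (D97_133_KO) by library size and 67 in siFBL with the compared groups alone, with 118 to 203 and 172 to 252 as each library was left out. Of 360 alternatives for 24 counts per list, 62 moved the count by over 1.5 times, 22 of them with 1 library left out. The guided shift in siFBL was 0.36 by 5' ends and 0.82 by 3' ends (21 sites). It was 0.40 with siCtrl 3 and 4 and 0.47 with siCtrl 1 and 2 (exact permutation p = 0.0667, the smallest 15 assignments allow). As each library was left out, the guided shift was 0.40 to 0.49 in siFBL and -0.20 to -0.085 in D97_133_KO (-0.20 and exact permutation p = 0.0286 without D97_133_KO 2). The stand-alone shift was -0.33 to -0.21 in siFBL and -0.29 to -0.17 in D97_133_KO, both lowest and past the exact permutation threshold without siCtrl 1; it was -0.15 and -0.11 with siCtrl 1 and 2, and -0.35 and -0.31 with siCtrl 3 and 4. With replicate as a block the counts were 3662 and 4760 positions and 148 and 190 RNAs, and the guided shift in siFBL 0.44 (exact permutation p = 0.125, the smallest 16 sign flips allow). Deviations of the site-to-flank ratios of libraries with the same number correlated at -0.0473 to 0.0306. No pairing by number was seen in these ratios, which cannot exclude a shared culture or preparation. By 5' ends alone, sign changes were Ser-AGA 18 (0.032 in siFBL, 0.044 in D97_133_KO), Ser-AGA 21 (-0.67 and -0.49), 18S nucleotide 178 (0.15, siFBL), and in D97_133_KO 18S Nm683 (-1.16), 28S Nm3887 (-1.36) and Thr-TGT 60 (1.14). By 3' ends alone they were Leu-TAG 32 (-0.69), Trp-CCA 26 (-0.87) and Glu-CTC 20a (0.20) in siFBL, and Ser-TGA 32 (-1.94), Tyr-GTA 46 (-2.13), 18S nucleotide 1677 (0.017), Ser-CGA 44 (0.087) and Cys-GCA 28 (0.71) in D97_133_KO. By library size Val-TAC (-0.075), Leu-AAG (-0.10) and Gly-TCC (-0.049) changed sign in siFBL, where the median of all RNAs was -0.304. Of 594 alternatives for 40 named positions 564 kept direction and call and 19 lost the call, of 1336 for 90 values at listed sites 1286, 22 and a further 23 gained it, and of 320 for 20 named RNAs 316 and 1. Single libraries decided Ser-TGA 18 in siFBL (-0.43, not called without siFBL 1) and 28S Nm4227 in D97_133_KO (1.32 without D97_133_KO 1, 1.58 without 2, 1.42 without 3, 1.34 without siCtrl 3, not called). Without any 1 siFBL library the shift of the 18S and 28S list was 0.23 to 0.25 (exact permutation p = 0.0571), and in D97_133_KO that list went from -0.0013 without siCtrl 3 to 0.08 without siCtrl 2. The cause of these changes was not tested.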

Other observations

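The comparison of both read ends was chosen after the data were seen. Outside the lists, the positions that rose by each read end alone in siFBL included Gln-CTG 19 and initiator Met 46 of tRNA, with log2 changes of 0.34 and 0.37 by 5' ends and 0.49 and 0.36 by 3' ends. Falls by each end included Met-CAT 28 (-0.58 by 5' and -0.98 by 3' ends), 6 positions before the wobble position, Phe-GAA 32 (-1.01 and -1.07) and Leu-AAG 64 (-2.74 and -0.59). The wobble position, which rose in siFBL, is among the flanks of Met-CAT 28, so the fall at Met-CAT 28 is not separate from that rise.

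Position 34 of the Leu-CAA copies of 105 to 108 nt, a stand-alone site, had a higher mean 3'-end score in D97_133_KO than in siCtrl, while on the copy of 84 nt the score was 0 in every group. These copies were singled out after their values were seen. On the chromosome 1 copy (248873855 to 248873960) it was 0.438 ± 0.0896 (SD, n = 4) in siCtrl, 0.520 ± 0.111 in siFBL and 0.617 ± 0.0171 in D97_133_KO, with a log2 change of read ends of -0.49 in D97_133_KO (edgeR adjusted p = 0.0418). With the 7 Leu-CAA copies summed the change was -0.26 and was not called (adjusted p = 0.0870).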
